A study of Capra hircus with 6 samples.

How the data were processed

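The series describes RNA sequencing of the medio-basal hypothalamus, the region at the base of the brain that includes the arcuate nucleus and median eminence, from adult Alpine goats (Capra hircus). Per the series' design text, the study used 18 goats, of which 5 were sampled in January in the follicular phase of the ovarian cycle, 5 in January in the luteal phase and 8 in mid-May in anestrus, the season without cycles. RNA was extracted from each goat, and for each condition 2 random equimolar mixes were sequenced. Each library is therefore a pool, and the sources used here do not say how many goats entered each pool or whether a goat contributed to both pools of its condition. The p-values consequently measure the spread between 2 pools per condition, not between goats. The luteal libraries were not analysed here, so the comparison made was follicular phase against anestrus, with 4 libraries.

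The deposited values are raw read counts per gene, given as whole numbers with no normalization. Per the labels' protocols, RNA was extracted with TriReagent and libraries were made with the Truseq stranded mRNA kit, which selects polyadenylated RNA. Per the submitters' processing notes, the authors used bcl2fastq 2.20, FastQC, TopHat2 2.1.1, Bowtie2 2.3.5.1, SAMtools 1.9 and featureCounts 2.0.0 to reach the deposited counts. The genome build, annotation release, strand setting and treatment of reads that map to several places are not given in the sources used here. Counts of genes with near-identical copies, such as ribosomal protein genes with processed pseudogenes, are uncertain for that reason, and no coordinates are printed.

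The table has 28907 rows, identified by NCBI gene identifiers. A symbol was paired with 27106 of them, of which 10744 were provisional LOC symbols, and 1801 rows had an identifier alone, 1770 of these being transfer RNAs. Of the identifiers, 28873 were found in the RefSeq gene table of the ARS1.2 assembly, which was used for synonyms and gene type. Library totals were 25292678 and 17090623 counts for follicular pools 1 and 2, and 14553821 and 17910056 for anestrus pools 1 and 2. A total of 7136 rows had 0 counts in all 4 libraries. The titles and the library names number the anestrus pools in opposite order, and the library names were used because the table's columns carry them.

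Genes were kept with edgeR's filterByExpr at its default settings, with a minimum count of 10 and a minimum total of 15, which left 16756 genes. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (estimateDisp, glmQLFit with robust estimation, glmQLFTest), with 1 mean per group and 2 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 are called changed. Log2 fold changes are follicular minus anestrus, so a negative value means a higher level in anestrus, and each is followed by its standard error. Levels are counts relative to the TMM-scaled library total (CPM) and are given as mean ± SD over the 2 pools of a group.

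Before the data were examined, 30 gene lists were written, covering pathways of seasonal reproduction and markers of the cell types that a dissected block of this region could hold. They named 602 gene entries, of which 554 matched a symbol in the table, directly or through a RefSeq synonym, and 48 did not. ALKAL2, of the photoperiodic list, was among the unmatched entries, because both tables name that gene FAM150B and give no synonym, so the list's counts and tests leave it out. Lists with at least 3 measured members, 29 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, 2-sided, and adjusted over the lists. Each was also tested with a correlation estimated from the data, and with fry. The 16 lists that passed with the preset correlation did not pass with the estimated one, so that p is printed beside each.

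The rule for named genes was also set before the data were examined. It took up to 10 genes in each direction with the largest change among those called, with a symbol, a mean of at least 1 CPM and no overlap between groups. To these it added 16 genes of seasonal and reproductive physiology whatever their result, up to 4 called members of each list, and the 2 members with the smallest p for a list that passed camera with no called member. Other genes named were chosen after their values were seen, as stated where they appear. The result of 1 gene that the rule names is not reported here.

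The edgeR steps were tested on simulated counts for this comparison, drawn for 16520 genes with 200 of them changed. Calls were made for 46% of genes simulated with a 2-fold change, 90.9% at 4-fold and 100% at 8-fold, and 7 of 159 calls were false. Of 50 random unchanged lists, camera called 0, and it called the list that had been raised. The simulated genes were drawn independently of each other, with a spread that followed the trend over expression level. The false calls therefore hold for such counts only. Lists of correlated members were not simulated, while correlations estimated in the real lists reached 0.75.

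Alternatives planned before the data were examined were size factors by DESeq2's method, library totals alone, no count filter, a filter on mean CPM of at least 1, the DESeq2 1.42.0 Wald test, limma-voom, edgeR without robust estimation, a replicate block under both numberings, other thresholds, and leaving out each library in turn. In the last case the lone library of a group is assumed to vary like the other group. Chosen after seeing the data were edgeR's newer quasi-likelihood fit (legacy = FALSE) and library totals without TSHB and CGA. The older fit had been planned as an alternative, but it is the default of the edgeR version used and was therefore the fit reported.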

Results

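Read counts per gene were compared between pools of medio-basal hypothalamus RNA from goats in the January follicular phase and from goats in mid-May anestrus, with 2 pools per group. Totals were 25292678 and 17090623 counts in follicular pools 1 and 2, and 14553821 and 17910056 in anestrus pools 1 and 2. Across genes, log2 CPM correlated at r = 0.9821 between the follicular pools and at r = 0.9714 between the anestrus pools. Pairs from different groups gave 0.9672 to 0.9773, so the anestrus pools were no closer to each other than to some follicular pools. Counts of pools within a group differed by more than sampling noise, with chi-square values per degree of freedom of 18.9 and 29.6, and none was treated as a repeat of another. The common biological coefficient of variation was 0.201.

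The comparison addresses how the medio-basal hypothalamus differs between the January follicular phase and mid-May anestrus, in which season and ovarian state differ together. TSHB, the beta subunit of thyrotropin, differed most by significance, at 1005 ± 275 CPM in anestrus and 5.80 ± 1.41 CPM in the follicular phase (SD, n = 2 pools each), 175-fold higher in anestrus. FAM150B (also known as ALKAL2), which encodes a ligand of the receptor tyrosine kinase ALK, was 29.4-fold higher in anestrus, and BPIFC, of the bactericidal permeability-increasing protein family, was 77.1-fold higher. EZH2, the histone H3 lysine 27 methyltransferase, was 7.86-fold higher in anestrus, at 234 ± 26.2 CPM against 29.7 ± 4.43 CPM. GFAP, the intermediate filament of astrocytes, was 2.01-fold higher in the follicular phase.

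In all, 34 of 16756 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 32 of them higher in anestrus and 2 higher in the follicular phase. The CPM of the 2 groups did not overlap for any of the 34. Over all genes tested the share without overlap was 38.3%, where 33.3% would be expected by chance. The lack of overlap is thus no separate support for the calls. At an unadjusted p under 0.05 there were 1432 genes, 713 higher and 719 lower in the follicular phase, where 838 would be expected by chance. Without follicular pool 1, 4 of the 34 calls remained, namely TSHB, FAM150B, BPIFC and EZH2. The number of calls was 95 without follicular pool 2, 810 without anestrus pool 1 and 583 without anestrus pool 2.

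**Figure D1:**
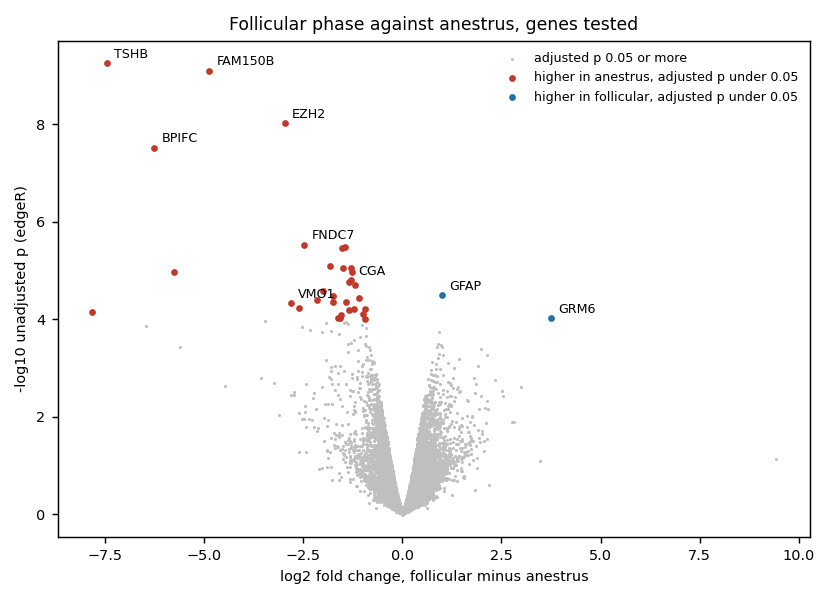
Log2 fold change, follicular minus anestrus (x axis), against -log10 of the unadjusted p of edgeR's quasi-likelihood test (y axis), with 1 point per gene tested. Coloured points are the 34 genes with an adjusted p under 0.05, of which 32 lie on the side higher in anestrus.

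The genes named by size of change covered several known functions, and most were higher in anestrus. TSHB had a log2 fold change of -7.45 ± 0.30 (gene 102185966, adjusted p = 6.66e-06, edgeR), FAM150B of -4.88 ± 0.25 and EZH2 of -2.98 ± 0.19. BPIFC had -6.27 ± 0.44, from 13 and 3 counts in the follicular pools and 354 and 588 in the anestrus pools. With so few follicular counts, its log2 fold change ranged from -7.292 to -5.794 over the alternatives. VMO1, named for the vitelline membrane outer layer, was 7.08-fold higher, but its anestrus pools lay apart, at 95.9 and 48.1 CPM. NEK2, a kinase of centrosome separation in mitosis, was 6.11-fold higher, FNDC7 5.57-fold, the interleukin receptor subunit IL17RB 4.49-fold, the homeobox gene SIX2 3.99-fold and the serum esterase gene PON1 3.54-fold. Without follicular pool 1, the calls of VMO1, NEK2, FNDC7, IL17RB, SIX2 and PON1 were lost, at log2 fold changes from -3.128 to -1.653. With all pools these ran from -2.823 to -1.823. The call of NEK2 was also lost in limma-voom (adjusted p = 0.0597). GRM6, a metabotropic glutamate receptor, was 13.5-fold higher in the follicular phase, from 96 and 38 counts against 3 and 4, with an adjusted p of 0.0492 (edgeR). That p was 0.0538 without robust estimation, 0.0532 in edgeR's newer fit and 0.0882 in limma-voom. The call of GRM6 was also lost without follicular pool 1, at a log2 fold change of 3.32 beside 3.757 with all pools.

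Genes of the photoperiodic response of the pars tuberalis, the melatonin-sensitive part of the pituitary next to the median eminence, were lower in the follicular phase than in anestrus as a list (camera adjusted p = 7.03e-06, and adjusted p = 0.346 with an estimated correlation). Of 17 measured members, 5 were lower in the follicular phase, 0 were higher and 12 did not pass. Adjusted over the list alone, 9 were lower and 2 higher. FAM150B, called lower in the follicular phase, was entered in this list as ALKAL2, matched no symbol under that name, and is not in these counts or tests. Besides TSHB and VMO1, the called members included CGA, the common alpha subunit of the glycoprotein hormones (2.46-fold), and DIO2, the deiodinase that activates thyroid hormone (log2 fold change -1.20 ± 0.17). CGA alone took 1.29% and 1.04% of all counts in the anestrus pools and 0.526% and 0.432% in the follicular pools. The calls of CGA and DIO2 were lost without follicular pool 1, at log2 fold changes of -1.429 and -1.252 beside -1.30 and -1.20 with all pools.

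EYA3, a transcriptional coactivator known to rise in the pars tuberalis on long days, did not pass, with a log2 fold change of -2.29 ± 0.56 and an adjusted p of 0.385 (edgeR). Its anestrus pools differed, at 658 and 1775 CPM, while the follicular pools averaged 248 ± 81.8 CPM. The log2 fold change of EYA3 was -2.84 without anestrus pool 1 and -1.36 without anestrus pool 2. Leaving either out removes the spread between them, so those fits cannot decide whether EYA3 changed. CHGA, the secretory granule protein chromogranin A, had a log2 fold change of 0.98 ± 0.33 and an adjusted p of 0.452 (edgeR), and passed in 7 of 15 alternatives. Among these were no count filter (adjusted p = 2.66e-05) and the DESeq2 Wald test (0.0457). Others used a replicate block or left out 1 pool. The log2 fold change was 1.31 without follicular pool 2, 1.442 without anestrus pool 1 and 0.676 without anestrus pool 2. As for EYA3, leaving out a pool removes the spread within its group, so those fits cannot decide whether CHGA changed. The CHGA pools lay at 1570 and 932 CPM in the follicular phase and at 808 and 460 CPM in anestrus. Its log2 fold change ranged from 0.581 to 1.442 over the alternatives.

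The list of anterior pituitary and pars tuberalis markers was also lower in the follicular phase (camera adjusted p = 0.000493, and adjusted p = 0.346 with an estimated correlation). Of its 15 measured members, 2 were lower, TSHB and CGA, which the photoperiodic list holds too, and 13 did not pass. Adjusted over the list alone, 3 were lower and 0 higher.

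**Figure D2:**
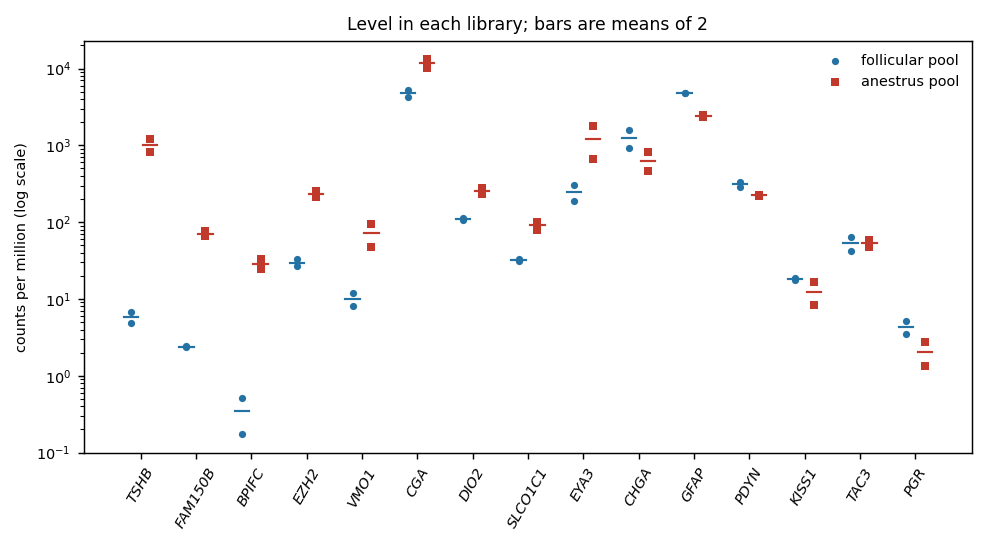
Level in CPM (y axis, log scale) of 15 named genes in each follicular pool (circles) and anestrus pool (squares), with bars at the mean of 2 pools. TSHB lies at 4.80 and 6.80 CPM in the follicular pools and at 1200 and 811 CPM in the anestrus pools.

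Among 24 measured genes of thyroid hormone metabolism, transport and signalling, 2 were lower in the follicular phase, 0 were higher and 22 did not pass. These were DIO2, at 110 ± 6.65 CPM against 253 ± 32.3 CPM in anestrus, and SLCO1C1, a thyroid hormone transporter of brain capillaries and astrocytes, at 32.0 ± 1.23 CPM against 90.6 ± 15.9 CPM. Adjusted over the list alone, 3 were lower and 2 higher. The list itself did not pass (camera adjusted p = 0.964, median log2 fold change 0.01). DIO3, the deiodinase that inactivates thyroid hormone, had a log2 fold change of -0.02 ± 0.60 at 3.24 ± 1.38 and 3.35 ± 2.70 CPM, a level and spread at which only a large change would be detectable. The call of SLCO1C1 was lost without follicular pool 1, at a log2 fold change of -1.45 beside -1.50 with all pools, as was that of DIO2.

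ALDH1A1, which makes retinoic acid from retinal, was 2.00-fold higher in anestrus (adjusted p = 0.0445, edgeR), the 1 called member of both the retinoic acid list (17 measured) and the dopamine list (13 measured). Its adjusted p was 0.0523 with the CPM filter and 0.0506 without robust estimation. The call was also lost without follicular pool 1 or 2, at log2 fold changes of -1.068 and -0.923 beside -1.001 with all pools. Neither list passed, with camera adjusted p of 0.183 and 0.584, although the retinoic acid list passed, lower in the follicular phase, without follicular pool 1 (0.0257) and without anestrus pool 2 (0.0341). Of 16 measured tanycyte markers, DIO2 was lower in the follicular phase and 15 did not pass (camera adjusted p = 0.0668). The tanycyte list passed, lower in the follicular phase, without follicular pool 1 (0.0477). TH, the rate-limiting enzyme of dopamine synthesis, had a log2 fold change of 0.10 ± 0.58. It was at 11.7 and 4.82 CPM in follicular pools 1 and 2, and at 11.8 and 3.83 CPM in anestrus pools 1 and 2. At that spread only a large change would be detectable.

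For the genes of the GnRH and kisspeptin network, 0 of 20 measured members passed singly, over all genes or adjusted over the list alone, while the list was higher in the follicular phase (camera adjusted p = 0.014, and adjusted p = 0.346 with an estimated correlation). The list's call was lost without anestrus pool 2 (adjusted p = 0.0729) and without follicular pool 2 (0.0965). Its median log2 fold change was 0.29, beside medians of 0.35 for neuron markers and 0.39 for synaptic genes. Without anestrus pool 2 the median, taken on log2 CPM, was 0.19 for the GnRH list and 0.2 for neuron markers. KISS1, the precursor of kisspeptin, was at 18.2 ± 1.09 CPM in the follicular phase and 12.3 ± 5.79 CPM in anestrus, a log2 fold change of 0.57 ± 0.33 that did not pass. Without anestrus pool 1 it was 1.146, and without anestrus pool 2 it was 0.195. The log2 fold change was 0.48 ± 0.16 for PDYN, the dynorphin precursor, 0.01 ± 0.23 for TAC3, the neurokinin B precursor, 0.55 ± 0.32 for NPVF, the precursor of RFamide-related peptides, and 0.38 ± 0.63 for GNRH1, and none of these passed. GNRH1 was close to the detection limit, at 1.24 ± 0.80 and 0.92 ± 0.11 CPM.

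None of the 22 measured sex steroid receptor and steroid-handling genes passed, and adjusted over the list alone 1 was lower, FKBP5, a chaperone partner of steroid receptors named after its value was seen (camera adjusted p = 0.612). PGR, the progesterone receptor, was at 4.37 ± 1.17 CPM in the follicular phase and 2.05 ± 1.02 CPM in anestrus, with an adjusted p of 0.55 (edgeR). Without anestrus pool 2 its log2 fold change was 1.761, and without anestrus pool 1 it was 0.66. ESR1, the oestrogen receptor alpha, had a log2 fold change of -0.10 ± 0.18.

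The list of feeding and energy balance peptides and receptors was higher in the follicular phase (camera adjusted p = 0.0299, and adjusted p = 0.473 with an estimated correlation), although its 1 called member of 30, PCSK1, went the other way. The list's median log2 fold change was 0.18, beside 0.35 for neuron markers and 0.39 for synaptic genes. PCSK1, the convertase that cleaves prohormones such as proopiomelanocortin, was 2.46-fold higher in anestrus, at 572 ± 46.1 CPM against 232 ± 27.1 CPM. Its call was lost without follicular pool 1, at a log2 fold change of -1.409 beside -1.300 with all pools. The list's call was lost without anestrus pool 2 (adjusted p = 0.362), without follicular pool 1 (0.245) and with the filter on mean CPM (0.0517). AGRP, NPY and POMC did not pass, with log2 fold changes of 0.03 ± 0.59, -0.20 ± 0.31 and -0.75 ± 1.04. The pools of a group lay apart for AGRP and POMC. POMC was 170 and 37.8 CPM in follicular pools 1 and 2, and 260 and 92.0 CPM in anestrus pools 1 and 2. AGRP was 7.79 and 2.38 CPM, and 7.01 and 3.11 CPM, in the same order. At such a spread only a large change would be detectable.

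Markers of neurons and glia were higher in the follicular phase as lists. Astrocyte markers had a camera adjusted p of 8.17e-07 (adjusted p = 0.346 with an estimated correlation), with GFAP the 1 called member of 11, at 4817 ± 18.2 CPM against 2398 ± 97.2 CPM. The call of GFAP was lost without follicular pool 1, at a log2 fold change of 1.027 beside 1.006 with all pools. Oligodendrocyte and myelin markers had a median log2 fold change of 0.76 and a camera adjusted p of 5.49e-07 (adjusted p = 0.473 with an estimated correlation), with 0 of 15 called singly and 9 adjusted over the list alone. Their mean log2 CPM, centred on the 4 pools, was 0.17 and 0.54 in follicular pools 1 and 2, and -0.08 and -0.63 in anestrus pools 1 and 2. MYRF, a transcription factor of myelination, and OPALIN, a protein of myelin, had log2 fold changes of 1.29 ± 0.33 and 0.74 ± 0.20. Oligodendrocyte precursor markers (8 measured, 0 called, 3 higher adjusted over the list alone) had a camera adjusted p of 0.000675 and adjusted p = 0.346 with an estimated correlation, with log2 fold changes of 0.83 ± 0.20 for BCAS1 and 1.06 ± 0.32 for GPR17. Adjusted over the list alone, 6 astrocyte markers were higher. The pituitary markers, the matrix genes and the ribosomal protein genes moved the other way, with medians of -0.64, -0.15 and -0.29.

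Synaptic transmission genes had a camera adjusted p of 3.99e-09 and adjusted p = 0.346 with an estimated correlation, and this was the 1 list that also passed fry (adjusted p = 0.0209). Of its 33 measured members 32 had a positive log2 fold change, 0 were called over all genes and 7 were higher adjusted over the list alone. GABRA2, a GABA receptor subunit, and CAMK2A, a synaptic kinase, had log2 fold changes of 0.85 ± 0.18 and 0.71 ± 0.16. The neuron markers (13 measured, 0 called) had a camera adjusted p of 0.00273 and adjusted p = 0.473 with an estimated correlation, with 0.47 ± 0.16 for SYT1 and 0.42 ± 0.15 for SYP, both proteins of synaptic vesicles. Their call was lost without anestrus pool 2 (adjusted p = 0.13) and without follicular pool 2 (0.0641). Astrocyte and oligodendrocyte markers moved in the same direction as these lists, with medians of 0.58 and 0.76, and the markers of neighbouring hypothalamic and thalamic areas had a median of 0.32 without passing (camera adjusted p = 0.0721).

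Immediate early genes, which neurons transcribe within minutes of activity, were higher in the follicular phase (camera adjusted p = 4.03e-05, and adjusted p = 0.394 with an estimated correlation), with 0 of 23 called and 1 adjusted over the list alone. The list's median log2 fold change was 0.49, beside 0.35 for neuron markers, 0.39 for synaptic genes, 0.58 for astrocyte markers and 0.76 for oligodendrocyte markers. The list's mean log2 CPM, centred on the 4 pools, was 0.47 in follicular pool 1, 0.06 in follicular pool 2, and -0.20 and -0.33 in anestrus pools 1 and 2. NPAS4 was at 9.03 ± 3.65 CPM against 2.27 ± 0.15 CPM and, uncalled here, passed in 7 of 15 alternatives. These included the DESeq2 Wald test (adjusted p = 0.0035) and no count filter (0.000182). Others used a replicate block or left out 1 pool, which removes the spread within its group and cannot decide whether NPAS4 changed. NR4A3 had a log2 fold change of 0.75 ± 0.24. Microglia and macrophage markers (15 measured, 0 called) had a camera adjusted p of 0.02 and adjusted p = 0.346 with an estimated correlation, a call lost without anestrus pool 2 (0.13) and without follicular pool 2 (0.0744). P2RY12 and CSF1R, receptors of microglia, had log2 fold changes of 0.62 ± 0.23 and 0.34 ± 0.17. Ependyma and choroid plexus markers (16 measured, 0 called) had a camera adjusted p of 0.00546 and adjusted p = 0.346 with an estimated correlation. Its members with the smallest p went opposite ways, at 0.55 ± 0.16 for ENPP2 and -0.68 ± 0.25 for CLIC6.

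Clock genes were lower in the follicular phase as a list (camera adjusted p = 0.00108, and adjusted p = 0.346 with an estimated correlation), with 0 of 20 called over all genes and 6 lower adjusted over the list alone. CIART, a repressor in the clock, had a log2 fold change of -1.37 ± 0.23 and an adjusted p of 0.0549 (edgeR), and passed in 9 of 15 alternatives. Among these were the DESeq2 Wald test (adjusted p = 0.00015), no count filter (3.65e-07) and DESeq2's size factors (0.0424). Others used a replicate block or left out 1 pool. The log2 fold change was -1.422 without follicular pool 2, -1.654 without anestrus pool 1 and -0.978 without anestrus pool 2. Leaving out a pool removes the spread within its group, so those fits cannot decide whether CIART changed. PER2, a period gene, had -1.03 ± 0.23. The list's call was lost without anestrus pool 2 (adjusted p = 0.0729) and without follicular pool 2 (0.0544).

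Extracellular matrix and collagen genes (30 measured) and meninges and fibroblast markers (12 measured) were lower in the follicular phase, with camera adjusted p of 0.00546 and 0.00378, and 0 members of either called. These became adjusted p = 0.346 and adjusted p = 0.473 with an estimated correlation. Adjusted over the list alone, 1 matrix gene and 2 meningeal markers were lower. The matrix proteoglycans DCN and LUM had log2 fold changes of -0.82 ± 0.16 and -0.60 ± 0.16. The matrix list lost its call without anestrus pool 2 (adjusted p = 0.0532) and without follicular pool 2 (0.0505), and the meningeal list without follicular pool 1 (0.0512). Ribosomal protein genes (43 measured, 0 called) were lower in the follicular phase, with a camera adjusted p of 3.86e-05 and adjusted p = 0.604 with an estimated correlation, and log2 fold changes of -0.51 ± 0.16 for RPL7 and -0.59 ± 0.18 for RPL10A. That call was lost without anestrus pool 1 (adjusted p = 0.4), in which ribosomal protein genes took 4.64% of counts against 3.31% to 3.68% in the other pools.

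The remaining lists did not pass camera. In the heat shock and unfolded protein response list, HSPA5, the main chaperone of the endoplasmic reticulum, was 1.92-fold higher in anestrus, at 1874 ± 65.7 CPM against 974 ± 7.43 CPM, and 17 of 18 members did not pass (camera adjusted p = 0.0607). The call of HSPA5 was lost without follicular pool 1 and without follicular pool 2, at log2 fold changes of -0.934 and -0.935 beside -0.944 with all pools. The lists for cholesterol synthesis, angiogenesis, cell cycle and neurogenesis, interferon response and antigen presentation, oxidative phosphorylation, endothelium and pericytes, and neighbouring hypothalamic and thalamic areas had no called member and camera adjusted p from 0.0721 to 0.949. The list of neighbouring areas (median log2 fold change 0.32) passed, higher in the follicular phase, without follicular pool 1 (0.0178) and without anestrus pool 1 (0.00717). Of the blood markers 1 was measured, so that list was not tested.

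**Figure D3:**
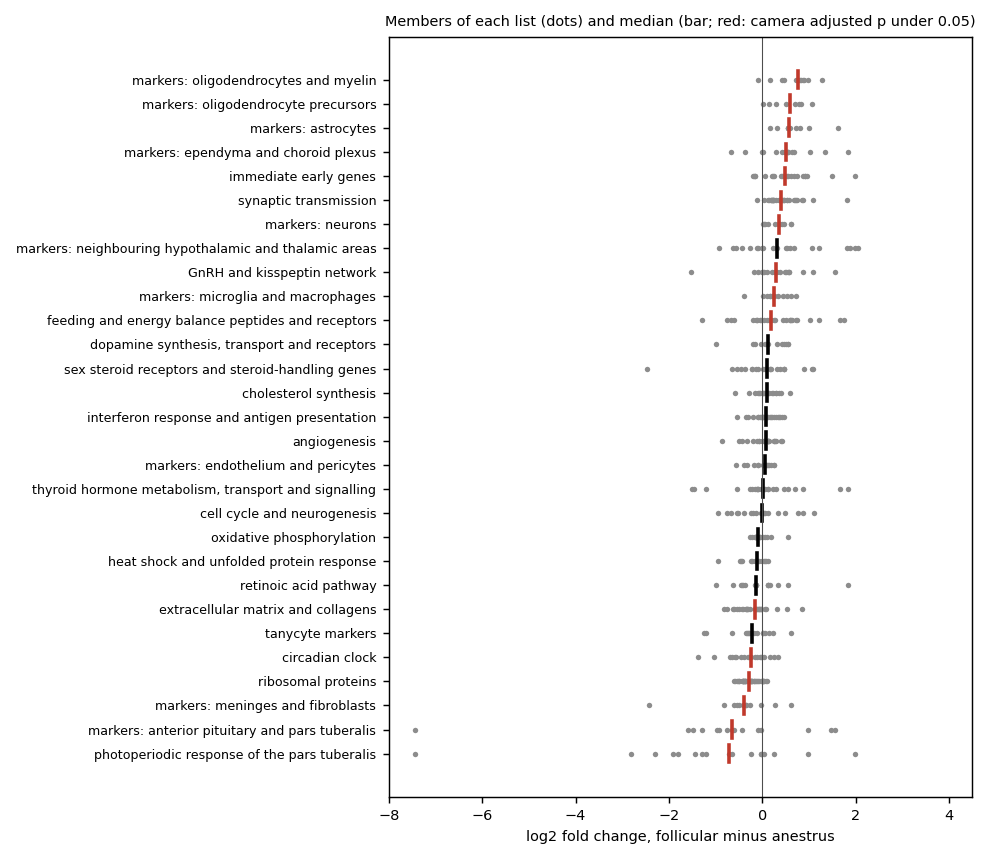
Log2 fold change, follicular minus anestrus (x axis), of each measured member (dots) of the 29 lists tested (y axis), with a bar at the list's median, red where the camera adjusted p was under 0.05 with the preset correlation. The median was 0.76 for oligodendrocyte and myelin markers and -0.71 for the photoperiodic list of the pars tuberalis.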

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

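EdgeR's newer fit and the totals without TSHB and CGA were chosen after seeing the data. The count of 34 changed genes stayed within 1.5 times under DESeq2's size factors (46), library totals (39), the CPM filter (33), limma-voom (30), no robust estimation (30), the newer fit (38), totals without TSHB and CGA (34) and a log2 fold change of at least 1 (32). It was 300 without a count filter, all 34 among them, where the fitted prior degrees of freedom became infinite instead of 8.75 at the median. The DESeq2 Wald test called 146 (43 higher and 103 lower in the follicular phase), for which the cause was not tested. An adjusted p under 0.01 left 7, and one under 0.1 gave 55, by construction. Leaving out 1 pool gave 4 to 810, with 1 residual degree of freedom: 4 without follicular 1, 95 without follicular 2, 810 without anestrus 1 and 583 without anestrus 2. The labels do not say what pools with the same number share, and 2 pairs are too few to treat them as paired. With a replicate block, 90 genes passed with numbers as in the library names and 130 with anestrus numbers as in the titles. Deviations of same-numbered pools correlated at 0.26 across genes with numbers as in the library names, a sign that turns with those of the titles. With the block as in the library names, the feeding list no longer passed (adjusted p = 0.0588) and the tanycyte list did (0.049), while in either numbering CHGA (0.0272 and 0.00127), CIART (0.0153 and 0.000362), NPAS4 (0.038 and 0.0136) and GABRA2 (0.0326 and 0.0272) passed. With the numbering of the titles, EYA3 (3.96e-25), DCN (0.00652) and BCAS1 (0.0361) passed too.

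The 16 lists became 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 1 with fry. Correlated members do not account for this in the synaptic, GnRH, matrix, pituitary, microglia and ependyma lists. Their estimated correlations, -0.01, -0.04, -0.03, -0.06, -0.02 and -0.04, lay below the preset 0.01, while oligodendrocyte markers had 0.75 and ribosomal protein genes 0.51. Astrocyte markers had an estimated 0.01, yet their unadjusted camera p went from 8.45e-08 to 0.0338. The estimated form draws on the 2 residual degrees of freedom of this design. Its p is therefore not a check on correlation alone, and how much of the loss comes from the few pools was not tested. With 1 pool left out, 12 to 18 lists passed.

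Of the 19 called genes among those named, 262 results under alternatives stayed past the threshold, 23 did not and 0 changed direction. TSHB, FAM150B, EZH2 and BPIFC passed in each alternative test. Of 35 uncalled named genes, 18 passed in at least 1 alternative. PER2, DCN, GABRA2, CAMK2A, BCAS1 and MYRF did so without a count filter and in the DESeq2 Wald test, OPALIN without a filter, and each of these 7 also without 1 anestrus pool, as did LUM, ENPP2, RPL10A, SLC17A6 and P2RY12. The directions that turned belong to uncalled genes, and the cause was not tested. DIO3 was 0.004 with DESeq2's size factors, 0.007 with library totals, 0.009 with the CPM filter, 0.276 in limma-voom, 0.062 in the newer fit, and 0.103 and 0.146 with the replicate block in either numbering. With the block, AGRP was -0.085 and -0.082 and TAC3 -0.020 and -0.019. With 1 pool left out, values ranged from -0.638 to 1.175 for DIO3, -1.051 to 0.729 for AGRP, -0.322 to 0.283 for TAC3, -0.657 to 1.122 for TH, -0.460 to 0.973 for GNRH1, -2.188 to 0.179 for POMC, -0.542 to 0.314 for NPY and -0.225 to 0.089 for ESR1.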

Other observations

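Tests on white matter in 1 pool, on the time of day and on endoplasmic reticulum chaperones were set before their results were seen, the time of day and chaperone criteria were revised after, and the other tests here were chosen after. The genes in the next paragraph and in the one after it were also chosen after their values were seen.

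The called genes outside the naming rule were all higher in anestrus. They included SHH, the hedgehog ligand, at 57.2 ± 2.02 CPM against 24.4 ± 1.60 CPM, PDE10A, a cyclic nucleotide phosphodiesterase (2.53-fold), ANOS1, a gene of X-linked Kallmann syndrome (2.66-fold), and EPCAM, an epithelial adhesion molecule (1.91-fold). The others were NMT2, AMPD3, ANGPTL2, SLC39A6, GJB7, SMC4, ATP8B4, BLNK and SCNN1B, at 2.14-fold to 3.38-fold. A transcribed pseudogene, LOC102168414, had 3 and 0 counts in the follicular pools and 52 and 83 in the anestrus pools, and LOC102169326 had 0 and 0 against 22 and 27. Among markers of neighbouring areas, SIM1, a transcription factor of the paraventricular nucleus, and SLC17A7, a glutamate transporter of cortex and thalamus, had log2 fold changes of 1.98 ± 0.52 and 1.81 ± 0.44, and did not pass over all genes. OXT, the oxytocin precursor, had 2.05 ± 0.81.

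With numbers as in the library names, pools 1 and 2 differed alike in both groups for some genes. With the anestrus numbers of the titles, these genes would differ in opposite directions in the 2 groups. Those given here were taken from the genes with the largest shared difference, and how many chance would give was not tested. DPM3 was 24.4 and 6.86 CPM in follicular pools 1 and 2, and 16.5 and 4.22 CPM in anestrus pools 1 and 2. MIF, NDUFB7, POMC, AGRP and TH differed in the same direction. TTR was 252 CPM in follicular pool 1 and 27.4 CPM in follicular pool 2, and 61.1 and 17.7 CPM in anestrus pools 1 and 2. VGF was 108 and 35.6 CPM, and 174 and 55.9 CPM, in the same order. RPLP2 was 227 and 107 CPM, and 242 and 84.6 CPM. GH1 went the other way, at 1.81 and 13.1 CPM, and 11.0 and 33.3 CPM. The labels name no batch, and no explanation of this difference was tested.

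TSHB, FAM150B, BPIFC and EZH2 were far higher in anestrus. A larger share of pars tuberalis in the anestrus pools could raise them. It would do so by the factor of CGA, the most abundant pituitary transcript here, if CGA came from that tissue alone at a constant level per cell. Their median log2 change relative to CGA was -4.27 (-4.66 to -3.87 over the 4 pairings of a follicular with an anestrus pool), with -6.15 for TSHB and -1.68 for EZH2. Neither assumption on CGA was tested, and CGA is itself a member of the photoperiodic list. Pars distalis tissue would bring GH1, which was 0.917% and 4.1% of TSHB in the anestrus pools, although goat growth hormone gene copies may share reads. For CGA, DIO2 and the other genes called at under 4-fold, tissue share and a change per cell cannot be told apart, because 6 pituitary transcription factors had a median log2 change of -0.63 with an SD of 0.33, between 0 and the -1.30 of CGA. The difference in season and ovarian state stays open for all of them, and season and ovarian state differ together in these 2 groups.

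The marker lists of neurons, astrocytes and oligodendrocytes passed camera as higher in the follicular phase, but none passed with an estimated correlation (adjusted p = 0.473, 0.346 and 0.473) or fry, and GFAP was the 1 member called. White matter in 1 pool as the whole source is argued against, because the oligodendrocyte median stayed at 0.51 or above without each pool in turn (0.51 to 1.06). The list also differed within groups, with centred mean log2 CPM of 0.17 and 0.54 in follicular pools 1 and 2. In anestrus pools 1 and 2 it was -0.08 and -0.63. Uneven white matter in more than 1 pool was not tested. A lower share of neural tissue in the anestrus pools may raise all 3 lists alike, and it cannot be told apart from a change in glia or from the dissection, which was not tested, because over pools glia exceeded neurons by 0.38 ± 0.19 (astrocytes) and 0.38 ± 0.20 (oligodendrocytes), ratios to the standard error of 2.05 and 1.89 against a critical value of 4.30. The first criterion, permutation of members between lists, would have counted against a common share, with p of 0.00195 for oligodendrocytes and 0.0031 for astrocytes against neurons (3 comparisons, 100000 permutations, 2-sided, the smallest 0.00465 after Benjamini-Hochberg adjustment). It was set aside after those p were seen because members are not replicates and can be correlated, a reason that holds for oligodendrocytes (estimated correlation 0.75) and neurons (0.27) but not for astrocytes (0.01).

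The clock list passed camera as lower in the follicular phase, but not with an estimated correlation (adjusted p = 0.346), fry (0.27) or without follicular pool 2 (0.0544) or anestrus pool 2 (0.0729), and 0 of 20 members were called. The labels give no hour of collection. If the groups were collected at different times of day, evening-phase genes and their opposite-phase partners could move in opposite directions. Their mean log2 changes were -0.48 (9 genes) and -0.07 (5 genes), a difference of -0.42 with an exact permutation p of 0.111, 2-sided, over genes that are not independent replicates. The criterion set beforehand would have read this as evidence against a difference in hour, and it was set aside after the value was seen, because a p that misses the threshold does not show that the sets moved alike. Hour, day length and ovarian state cannot be told apart here.

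A first hypothesis of a different kind was that NEK2, SMC4 and EZH2, known from dividing cells, were higher in anestrus because more cells were dividing. The 12 measured cell cycle genes had a median log2 change of -0.22 with an SD of 0.51, against -1.34 for the smallest change of these 3 genes. Of the 12, 9 had a mean CPM under 5, such as MKI67 with a log2 change of 0.49 ± 0.67, as had NEK2 itself, while the 3 more abundant ones, PCNA, CCNA2 and MCM6, had -0.54 ± 0.17, -0.39 ± 0.21 and -0.15 ± 0.18. The bounds on the SD and on the level were added after the values were seen. To count against dividing cells, the first criterion asked for a median above -0.5 with MKI67 and TOP2A (-0.52 ± 0.52) not both below it, which was met, but so few of the genes reached a mean CPM of 5 that the hypothesis stays open. A further hypothesis was that HSPA5 rose in anestrus with other chaperone and stress genes of the endoplasmic reticulum. Without HSPA5, the 5 such genes had a mean log2 change of -0.28 against -0.06 for 11 other members of the list, with an exact permutation p of 0.0247, 2-sided, over members that are correlated. That p met the criterion set beforehand. A check over pools, added after it was seen as for the neural lists and run on log2 of CPM plus 0.1, gave a difference of -0.23 ± 0.21, a ratio to the standard error of 1.12 against a critical value of 4.30, so this hypothesis stays open too.

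The 4 pools can be split into 2 and 2 in 3 ways, too few for a share under 0.05. The real split called 34 genes and the highest of the others called 0, so 1 of the 3 splits gave as many.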
